A study of Pseudomonas aeruginosa with 5 samples.

How the data were processed

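The samples were total RNA libraries from anaerobic serum-bottle cultures of Pseudomonas aeruginosa PAO1, 3 with FNA and 2 without. Per the labels, treated cultures received FNA at 0.1 mg N/L once they had grown for 11 h, water was given in its place to the controls, and cells were collected at 13 h. The labels speak of 3 cultures per condition, while 5 samples were described in the sources used here, and how many libraries entered each average is not given in them. Libraries were strand-specific, per the labels. Each sample was assigned to control or FNA from its labelled FNA level.

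The authors deposited averaged RPKM values (reads scaled to gene length and to the mapped reads of a library), a single value per gene and condition, per the file headers. Beside them the authors' deposited table gives a log2 fold change, a test statistic (a score whose computation is not stated), a p-value and a q-value for FNA over control. Cufflinks 2.2.1 and Cuffdiff are named in the submitters' processing notes, without their roles. The aligner, the genome build, the annotation and any read filter are not given in the sources used here. The deposited log2 values differ from the log2 ratio of the deposited RPKM columns by at most 1.4e-05, so the ratios reported here were recomputed from the RPKM columns.

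The table used here holds 3252 genes, all marked significant, with q-values in the authors' deposited table up to 0.05. The smallest changes listed are 0.46 and -0.47 on the log2 scale. The lowest p-value in the authors' deposited table, 5e-05, is shared by 1974 genes, which all have a q-value of 0.000163, so p-values do not rank these genes. The relation between rank, p-value and q-value in the authors' deposited table implies an adjustment over at least about 6449 tests, and at least 168 rows with a p-value at or below the highest one listed beyond those used here. Counts and shares therefore refer to the genes used here, and a gene outside them is described as not analysed here. In the reference gene table of assembly GCF_000006765.1 (ASM676v1), which was used to look up locus tags and symbols, 3238 of the 3252 loci matched and 14 did not. That table names 5697 genes. Symbols come from the deposited table and, where it gives only a locus tag, from the gene lists; the reference table adds no symbol to the largest changes.

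Because each condition has a single averaged value, no standard deviation, no n and no test of a difference could be computed, and leaving out replicates was not possible. Precision depends on the number of reads behind each average, which is unknown: RPKM without gene counts gives no depth, and genes of a few RPKM are the least certain. Calls are those of the authors' deposited table. Near-identical copies and overlapping genes can share reads, and how these were counted is not stated.

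Before the data were examined, 32 gene lists with 518 genes were fixed, of which 322 genes were in the table. For each list the members called higher and lower were counted, and the percentile of its median log2 ratio was taken among 10000 random lists of the same size, drawn from the other listed genes in the same 10 classes of mean RPKM, so a list is set against other called genes. This was done for the 29 lists with at least 3 listed members. A Fisher exact test of called members against all genes tested had been planned and was not run, since every gene used here is a called gene. The percentile step was tested on simulated data made by shuffling the log2 ratios of the 3252 genes. Shuffling removes any link between log2 ratio and mean RPKM, and simulated members were picked from genes of all levels. The simulation therefore does not test the matching on mean RPKM. Each simulated list was set against fewer random lists than the 10000 used for the data. Without a shift, 1 of 20 simulated lists of 7 genes, 2 of 20 of 20 genes and 1 of 20 of 50 genes fell outside the central 95%. With a shift of 2 on the log2 scale, 16, 19 and 20 of 20 did. Smaller shifts were also simulated but are not reported here, so the power for them is not given. Lists of fewer than 7 genes were not simulated. Random and simulated lists drew genes singly, whereas several fixed lists hold genes of the same operon, which can move together. The simulated rates therefore need not hold for such lists.

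Named genes followed a rule fixed beforehand: the 10 largest rises and 10 largest falls among called genes with a symbol and at least 10 RPKM in either condition, up to 4 members per list with the largest absolute log2 ratio, and 22 genes always considered, of which 13 were in the table. Outside this rule, PA1332, PA1168, rplS, hscA, nuoA, glcB, aceA, fumC1, lon, fliE, cyoA, cyoB and cyoE in the results, and the 14 gene groups and further genes of the closing observations, were chosen after their values were seen. A planned filter on genes with a mean below 1 RPKM removed none. No pseudocount was added, since no listed value was 0. Alternatives were pseudocounts of 0.1 and 10, a mean of at least 10 RPKM, rescaling by the median ratio, a log2 ratio of at least 1, a q-value of at most 0.01 and, added after seeing the data, equal sums of RPKM. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.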

Results

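Transcripts of Pseudomonas aeruginosa PAO1, a widely used laboratory strain that respires nitrate when oxygen is absent, were measured by RNA sequencing in anaerobic cultures given free nitrous acid (FNA, the protonated form of nitrite) at 0.1 mg N/L or the same volume of water. Cultures were sampled 13 h after inoculation, 2 h after the addition. The samples comprised 3 FNA libraries and 2 control libraries. The values available were a single mean RPKM per condition for each gene, as averaged by the authors, so no spread between replicates can be given and the depth of the libraries is unknown. Throughout, a gene "rose" or "fell" when it was called at a q-value under 0.05 in the authors' deposited table, and log2 ratios are FNA over control. The genes rplS, hscA, nuoA, glcB, aceA, fumC1, lon, fliE, cyoA, cyoB and cyoE are named below outside the rule fixed beforehand and were chosen after their values were seen.

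The question was which genes changed when FNA was added. Genes of nitric oxide removal and of iron-sulfur cluster assembly rose, whereas genes of the ribosome and the ATP synthase, and most genes of the NADH dehydrogenases and the citric acid cycle, fell. Of the 3252 genes in the table used here, 1134 rose and 2118 fell, the latter being 65.1%. The median log2 ratio was -1.17 over all listed genes, 1.51 among the genes that rose and -1.76 among those that fell. Of these genes, 855 were higher and 1793 lower by at least 1 on the log2 scale. The excess of falls depends on the scaling between the columns. With the median of the listed genes taken as the reference, a shift of 1.17, the split is 50% by construction. Values relative to that median are given below as centred values. That median covers called genes only, so genes that were not called had no part in it. A reference over all genes may differ. Directions that turn after centring therefore show dependence on this reference, not that genes failed to fall.

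Among genes with a symbol and at least 10 RPKM in either condition, the largest rise was that of liuR, the regulator of the liu genes of leucine and isovalerate breakdown, from 25.5 to 1409 RPKM (55.3-fold). Its neighbour liuA, annotated as isovaleryl-CoA dehydrogenase, rose from 22.6 to 382 RPKM. The acetyl-CoA synthetase gene acsA rose 12.9-fold, from 159 to 2047 RPKM, and the urocanase gene hutU of histidine breakdown rose from 11.2 to 123 RPKM. Other large rises were those of himA, which encodes a subunit of the DNA-bending integration host factor (from 640.0 to 6818 RPKM), nfuA, an iron-sulfur carrier (from 302 to 3519 RPKM), and the regulator genes cifR (log2 ratio 3.77) and czcR (log2 ratio 3.99). The sensor gene pprA and the prepilin peptidase gene fppA started from 2.95 and 2.45 RPKM and reached 37.0 and 27.5 RPKM.

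Of the 10 largest falls among such genes, 4 were in the kdp operon. The kdp genes encode an inducible potassium pump and its regulators, and kdpC fell 31.6-fold, from 173 to 5.47 RPKM, while kdpB, kdpD and kdpE had log2 ratios of -4.42, -4.48 and -4.51. The exoribonuclease gene pnp fell from 612 to 23.3 RPKM, and rbfA, a ribosome maturation factor, fell from 205 to 9.85 RPKM. The succinate dehydrogenase gene sdhA fell 21.4-fold, from 759 to 35.5 RPKM. The remaining genes among these 10 were dhcB (log2 ratio -4.55), holA (log2 ratio -4.43) and fabH2 (log2 ratio -4.36). Some genes without a symbol, chosen after their values were seen, moved further: PA1332 rose from 1.47 to 211 RPKM and PA1168 fell from 1189 to 29.6 RPKM. The rise of PA1332 starts from a low control value and had a q-value of 0.0208 in the authors' deposited table, against 0.000163 for PA1168.

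**Figure D1:**
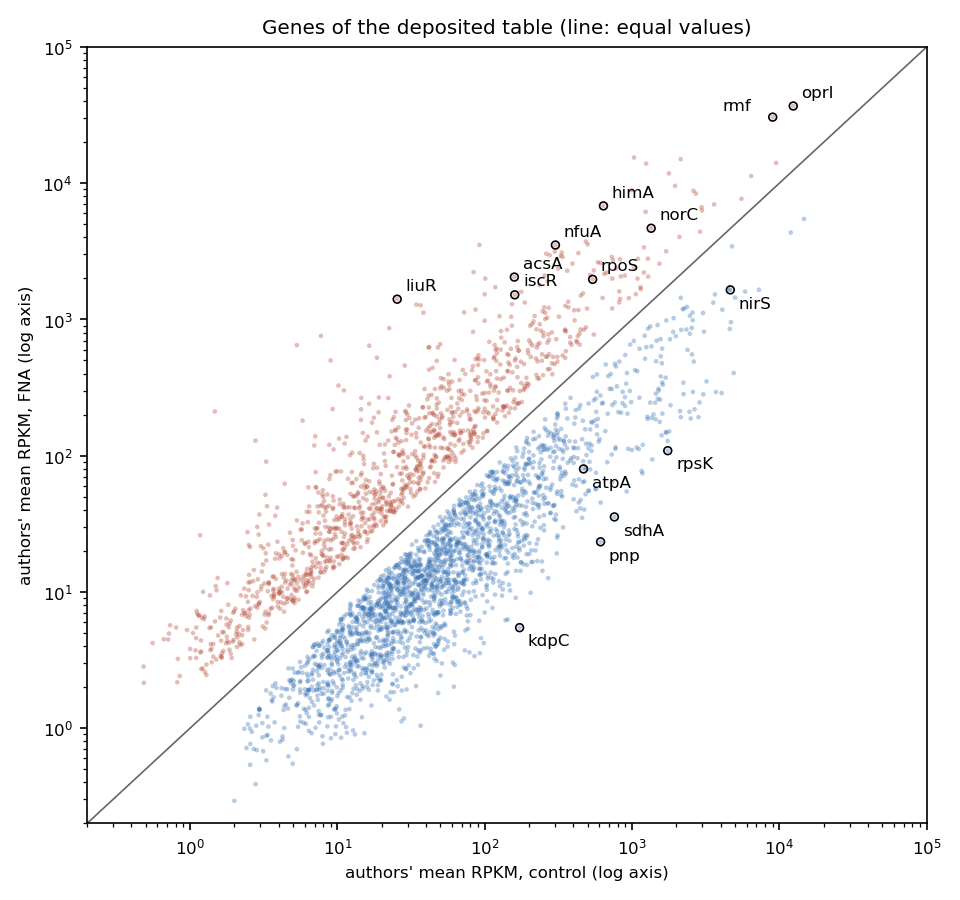
Mean RPKM of each of the 3252 listed genes in control (x axis, log scale) and FNA cultures (y axis, log scale), with genes that rose in red, genes that fell in blue and selected genes circled. The 1134 genes above the line of equal values include liuR (from 25.5 to 1409 RPKM), and the 2118 genes below it include kdpC (from 173 to 5.47 RPKM); the empty band along the line is the range of small changes that the table used here does not list.

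Along the denitrification pathway, genes of the nitric oxide step rose while most listed genes of the nitrate, nitrite and nitrous oxide steps fell. After centring the listed genes of the nitrite step split evenly, since nirJ, with a log2 ratio of -1.11, moved to 0.054. The list of nitric oxide reduction and detoxification had 4 members and all 4 rose, with a median log2 ratio of 1.93. The nitric oxide reductase genes norC and norB rose from 1349 to 4672 RPKM and from 673 to 2208 RPKM, norD rose 4.35-fold, and fhp, which encodes the nitric oxide-detoxifying flavohemoprotein, rose from 550.0 to 2293 RPKM. The nitrite reductase gene nirS, whose product forms nitric oxide, fell from 4648 to 1649 RPKM, a log2 ratio of -1.49 and a centred value of -0.33. In the nir list 1 of 4 listed members rose, nirQ (from 250.2 to 798 RPKM), and 3 fell; after centring 2 lay above and 2 below the median of the listed genes.

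The membrane-bound nitrate reductase genes narG, narH, narJ and narI all fell, narG from 60.6 to 19.7 RPKM and narI from 165 to 28.5 RPKM. In the nitrate reductase list 5 of 6 listed members fell and the list median was -1.87, or -0.71 after centring. All 3 listed nos genes fell, including the nitrous oxide reductase gene nosZ (from 464 to 181 RPKM) and nosL (log2 ratio -2.22), and their median of -1.36 became -0.19 after centring. Both listed denitrification regulator genes rose, narX from 27.2 to 51.9 RPKM and narL from 60.2 to 106 RPKM. None of these lists stood outside the central 95% of 10000 random lists matched on mean RPKM. The nitric oxide list lay at percentile 91.2, the nitrate reductases at 14.4, the nir list at 24.2 and the nos list at 35.3. For lists this short the central 95% was wide, from -2.52 to 2.54 for the nitric oxide list and from -2.88 to 2.43 for the nos list. Lying inside it therefore does not show that these genes moved like other called genes. Not analysed here are 6 of the 12 members of the nitrate reductase list, 8 of the 12 of the nir list, 3 of the 6 of the nos list and 3 of the 5 regulators, napA, dnr and anr among them.

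**Figure D2:**
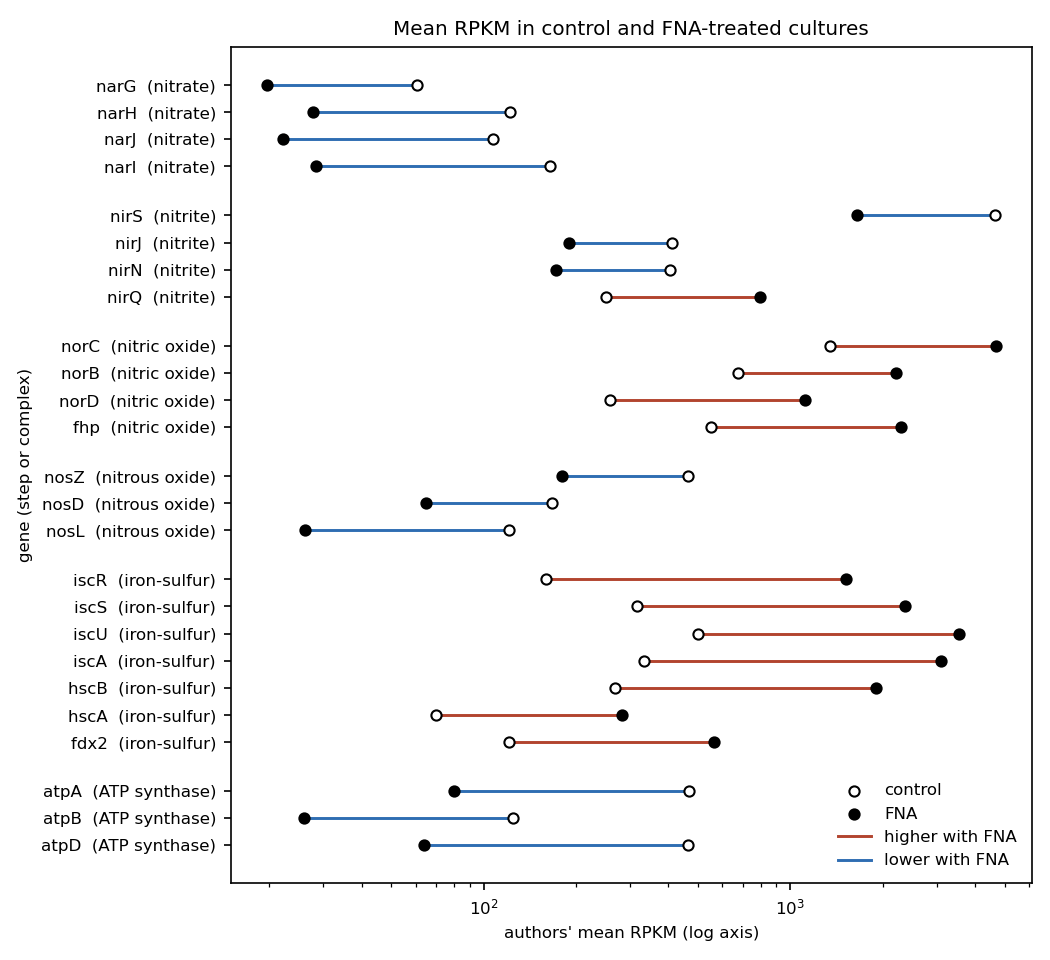
Mean RPKM per condition (x axis, log scale) of genes of denitrification, iron-sulfur cluster assembly and ATP synthase (y axis), with open circles for control, filled circles for FNA, red lines for genes higher and blue lines for genes lower with FNA. All 4 nitric oxide genes rose, norC from 1349 to 4672 RPKM, whereas nirS fell from 4648 to 1649 RPKM; on values centred on the median of all listed genes, nirJ lies above that median.

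The iron-sulfur cluster assembly operon rose as a whole. All 7 members rose, with a median log2 ratio of 2.83, at percentile 99.8 of the matched random lists, and a centred median of 4.0. The regulator gene iscR rose from 160.0 to 1517 RPKM, the cysteine desulfurase gene iscS from 316 to 2365 RPKM and iscA from 334 to 3099 RPKM. The smallest rise of the operon was that of hscA, from 69.9 to 283 RPKM, and the chaperone partner gene hscB rose from 267 to 1906 RPKM.

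Ribosomal protein genes fell together, also after centring. All 50 listed ribosomal protein genes, of 53 in the list, fell, and their median of -2.78 was below that of every matched random list. The median level of these genes was 1695 RPKM in control and 247 RPKM with FNA. The steepest falls included rpsK (from 1749 to 109 RPKM), rpsC (from 2827 to 192 RPKM) and rplP (from 4058 to 288 RPKM), and the mildest was rplS (from 777 to 452 RPKM). After centring the list median remained negative at -1.61, with 46 of the 50 genes below the median of the listed genes and 4 above it, rplS among the latter.

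All 9 ATP synthase genes fell, with a median of -2.55 at percentile 0.23; atpA, the alpha chain gene, fell from 468 to 79.9 RPKM and atpG from 506 to 55.2 RPKM. Among the NADH dehydrogenases 17 of 18 listed genes fell, with a median of -2.36 at percentile 0.15, nqrE falling from 59.0 to 7.24 RPKM and nuoN from 94.6 to 13.6 RPKM; nuoA alone rose, with a log2 ratio of 0.49. In the citric acid cycle and glyoxylate shunt 15 of 18 listed genes fell and the list median of -2.83 was below that of every matched random list. The 4 largest falls were those of sdhA, sdhB (from 919.6 to 54.7 RPKM), sdhD (from 1163 to 77.2 RPKM) and the succinyl-CoA synthetase gene sucD (from 612 to 45.3 RPKM). The 3 that rose were the malate synthase gene glcB (log2 ratio 1.76), the isocitrate lyase gene aceA (log2 ratio 0.60), both of the glyoxylate shunt, and the fumarase gene fumC1 (log2 ratio 2.33). Centred medians of these lists were -1.38, -1.19 and -1.66, so the direction held under that scaling.

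Terminal oxidase genes moved both ways, with 8 of 13 listed members rising and a median of 1.07 at percentile 94.7; with a mean of at least 10 RPKM, which leaves out cyoA, cyoB and cyoE, 5 rose and 5 fell, at percentile 68.9. The genes of the high-affinity Cco1 oxidase fell, ccoN1 from 254 to 44.4 RPKM and ccoO1 from 196 to 26.0 RPKM. The listed Cco2 oxidase genes fell too, by less, whereas cox genes rose, coIII from 65.2 to 242 RPKM. In glucose metabolism by the Entner-Doudoroff route 5 of 6 listed genes rose, zwf from 632 to 1439 RPKM, and the porin gene oprB fell from 159 to 39.4 RPKM; the list median was 0.74, at percentile 70.5. Of 3 listed glycerol genes 2 rose, glpF (log2 ratio 0.81) and glpD (log2 ratio 0.74), at percentile 58.8. The arginine and fermentation list split: the acetate kinase gene ackA (from 41.6 to 276 RPKM), the phosphate acetyltransferase gene pta (from 43.9 to 171 RPKM) and uspK rose, and 5 others, including the antiporter gene arcD (from 292 to 81.0 RPKM), fell, a majority that turned to 6 of 8 above the median after centring. That list lay at percentile 54.1.

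Stress genes did not move as a block. Of 10 listed oxidative stress genes 4 rose and 6 fell (percentile 48), a majority that became 5 above and 5 below after centring. The glutathione reductase gene gor (from 145 to 483 RPKM) and ankB (from 10.7 to 35.7 RPKM) rose, and the catalase genes katA (from 706 to 310.1 RPKM) and katE (from 23.7 to 2.1 RPKM) and the glutaredoxin gene grx (from 127 to 18.5 RPKM) fell. Of the 20 members of the list 10 are not analysed here, katB, ahpC and ohr among them. In the heat shock list 10 of 12 listed genes fell, groEL from 531 to 108 RPKM and dnaK from 297 to 128 RPKM, while the membrane protease gene htpX rose from 19.4 to 120.4 RPKM and lon rose with a log2 ratio of 0.87; the median of -1.25 lay at percentile 40.8, and after centring 5 of 12 were above the median of the listed genes. Of 12 listed DNA repair and SOS genes 7 rose, among them recA (from 819 to 1606 RPKM) and imuA (from 49.2 to 174 RPKM), and 5 fell, among them mutS (from 52.4 to 7.29 RPKM) and uvrA (from 35.5 to 7.39 RPKM), at percentile 88.9; counting only changes of at least 1 on the log2 scale, the majority turned, with 3 rising. The stationary-phase sigma factor gene rpoS rose 3.64-fold, from 540.5 to 1969.7 RPKM.

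Pyocin genes, which encode bacteriocins, fell in 23 of 25 listed cases, PA0622 from 5860.5 to 1602 RPKM, while the activator gene prtN (from 1237 to 6168 RPKM) and the immunity gene imm2 (from 2141 to 15027 RPKM) rose. Their median of -1.20 lay at percentile 4.88, or 0.66 when lists were matched after centring. After centring 12 were above and 13 below. In the Pf prophage 7 of 11 listed genes fell, PA0724 from 98.5 to 26.7 RPKM, and 4 rose, PA0715 from 89.3 to 519 RPKM, a majority that turned after centring, with 6 above; the list lay at percentile 64. All 3 listed ribonucleotide reductase genes fell, nrdA from 175 to 63.9 RPKM and nrdB from 521 to 156 RPKM, with 1 of the 3 above the median after centring, at percentile 29.5; nrdD and nrdJa are not analysed here.

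Among iron genes, 7 of 10 listed pyoverdine genes rose, including pvdF (from 8.37 to 38.9 RPKM) and fpvR (log2 ratio 2.16), and 3 fell, including pvdH (from 6.19 to 1.29 RPKM). The median of 1.13 lay at percentile 97.4, or 99.0 when lists were matched after centring. With a mean of at least 10 RPKM only 3 members are left, all of which rose, and pvdS is not analysed here. Of the other iron uptake and storage genes 1 of 3 listed rose, bfrB (from 2898 to 4410.1 RPKM), and 2 fell, including feoB (from 8.52 to 3.31 RPKM), at percentile 46.4; after centring 2 lay above. None of the 11 pyochelin genes is analysed here. In the copper list PA2807 rose from 1.23 to 10.0 RPKM and cueR, listed at 189.6 and 86.9 RPKM, fell; after centring both lay above the median. Of 9 listed efflux genes 4 rose and 5 fell, at percentile 50.1, with mexZ, the repressor gene of the mexXY pump, rising from 50.9 to 323 RPKM and mexX falling from 19.8 to 3.37 RPKM. In sulfate assimilation 1 of 6 listed genes rose, the regulator gene cysB (from 229 to 492 RPKM), and 5 fell, at percentile 70; after centring all 6 lay above the median.

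Surface structures gave mixed lists. Type IV pilus genes rose in 7 of 13 listed cases, among them pilC (from 90.7 to 546 RPKM), pilG (from 272 to 1218 RPKM) and pilM (from 119.8 to 496 RPKM). The median of 1.21 lay at percentile 98, outside the central 95%, but at 96.3, inside it, when lists were matched after centring. With 6 of 13 falling, that median is the smallest of the rises, and the mean log2 ratio was 0.44. Flagellar genes fell in 14 of 20 listed cases, motB from 136 to 26.0 RPKM and fliI from 119 to 28.9 RPKM, while fliE rose from 352 to 842 RPKM; the list lay at percentile 43.8 and its majority turned after centring, with 12 of 20 above. All 9 listed exopolysaccharide genes fell, pslL from 65.3 to 8.39 RPKM and, at low levels, pelD from 3.3 to 0.58 RPKM. Their median was -1.50 at percentile 32.8, and 2 of them lay above the median of the listed genes after centring.

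Of 13 listed quorum sensing and virulence genes 6 rose and 7 fell, at percentile 67.4, a majority that turned after centring with 10 above. The regulator gene lasR (from 364 to 2279 RPKM), the lectin gene lecA (from 8.12 to 46.4 RPKM) and rhlA of rhamnolipid synthesis (from 9.35 to 41.4 RPKM) rose, and the autoinducer synthase gene rhlI fell from 234 to 43.6 RPKM. Of 7 listed type III secretion genes 3 rose, including the exoenzyme gene exoS (from 11.3 to 26.8 RPKM), and 4 fell, at percentile 68.8, whereas all 7 lay above the median after centring. In the division and cell wall cluster 5 of 6 listed genes rose, including mraW (from 270.3 to 776 RPKM), ftsW (from 118 to 317 RPKM) and the division ring gene ftsZ (from 818 to 1333 RPKM), at percentile 71.7.

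**Figure D3:**
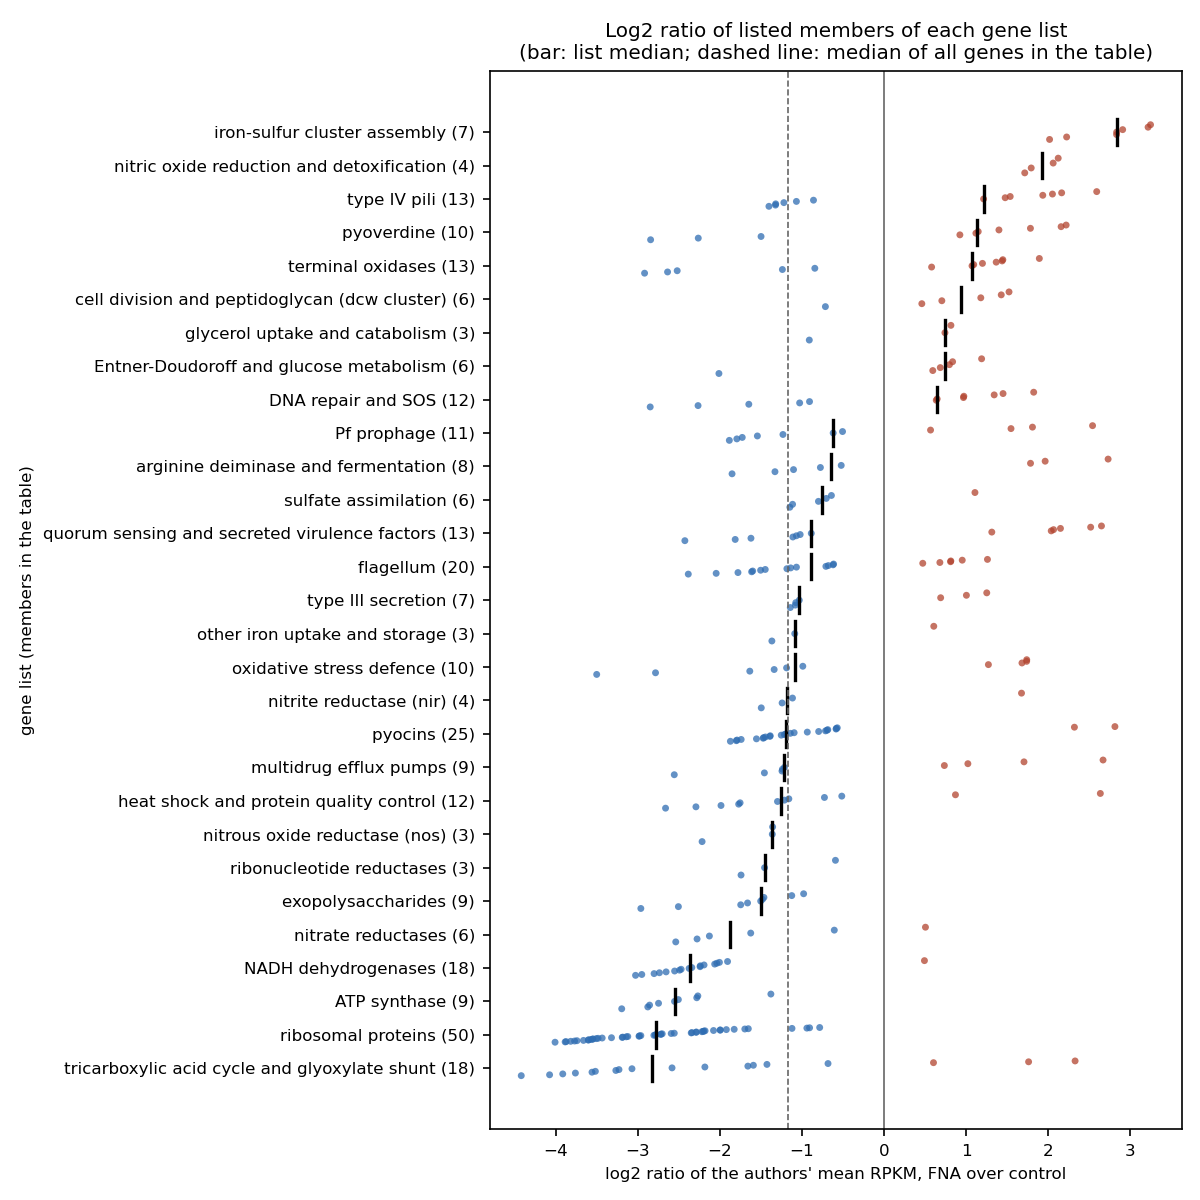
Log2 ratio of FNA over control (x axis) for each listed member of the 29 gene lists with at least 3 members in the table (y axis, number of members in parentheses), with black bars for list medians and a dashed line at the median of all listed genes, -1.17. Ribosomal protein genes had a median of -2.78 and iron-sulfur cluster assembly genes 2.83; list medians between the dashed line and 0 change sign when values are centred on that median.

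Of the 29 lists with at least 3 listed members, 4 lay below the central 95% of matched random lists, 2 lay above it and 23 lay inside; with lists matched after centring, 7 lay outside. These percentiles describe the 2 averaged profiles and carry no replicate error, since the authors' test behind each call cannot be repeated from averaged values.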

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

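Among the settings, equal sums of RPKM over the listed genes was chosen after seeing the data; it moved each log2 ratio by -0.17 and changed no direction, since no listed change is that small. Omitting the filter on low values moved nothing, because no gene had a mean below 1 RPKM. Apart from rescaling by the median ratio, which makes it 50%, the split of 1134 rises and 2118 falls stayed near 65.1% falls with a mean of at least 10 RPKM (65.2%), a q-value of at most 0.01 in the authors' deposited table (66.0%) and a log2 ratio of at least 1 (67.7%). A pseudocount of 10 lowered the genes at least 1 higher on the log2 scale from 855 to 557 and those at least 1 lower from 1793 to 1188, as it shrinks ratios of low genes by construction. Rescaling by the median ratio turned the majority in 7 lists that had more members lower, leaving below the median 2 members of the arginine and fermentation list, 5 of the Pf prophage, 1 of the other iron genes, 8 of the flagellum, 3 of quorum sensing and virulence, 0 of type III secretion and 0 of sulfate assimilation; 13 pyocin genes stayed below. Of the log2 ratios of 130 genes considered for the text, 3 changed sign, all under that rescaling: rplS moved to 0.39, nirJ to 0.054 and cueR to 0.044. Many of these 130 genes were picked for large log2 ratios, so few could cross a shift of 1.17. Over all genes used here, the same rescaling lowered the falls from 2118 to 1626 and raised the rises from 1134 to 1626. These turns follow from the shift of 1.17, which exceeds the size of the falls that turned. That shift is the median of called genes only and leaves out genes that were not called. The turns therefore do not decide the direction of these lists or genes. The same rescaling, which also changes the mean RPKM used for matching, put 7 lists, against 6, outside the central 95% of random lists: pyocins (percentile 0.66) and pyoverdine (99.0) joined and type IV pili (96.3) left. With equal sums the same 6 lists lay outside. With a log2 ratio of at least 1, DNA repair and SOS turned to 3 rises, and fewer members were left for arginine and fermentation (3 lower), pyocins (15 lower), sulfate assimilation (2 lower), the Entner-Doudoroff list (1 higher), the glycerol list (0 higher) and the division cluster (3 higher). With a mean of at least 10 RPKM, which leaves fewer genes, the other iron genes turned to 0 lower and type III secretion to 1 lower, and 3 pyoverdine genes and 5 terminal oxidase genes were higher and 5 exopolysaccharide genes lower; 7 lists, against 6, then lay outside the central 95% of random lists, pyoverdine joining at percentile 99.0. None of the other counts computed under these settings, for lists or for all genes, moved by over 1.5 times or turned. Quantile normalization, other tests, leaving out replicates and estimated correlations in set tests were not run, as they need values per library. No paired analysis was possible because the columns hold averages. Depth is unknown, so the precision of genes with few RPKM cannot be given.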

Other observations

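Of the tests in this part, those on the scaling factor, on slower growth, on the order of genes within operons and on rising operons were chosen after the results were seen, as were the gene groups described here. Genes of branched-chain amino acid breakdown and its neighbours rose in all 11 listed cases, with a median log2 ratio of 3.07. Next to the leucine dehydrogenase gene ldh (from 126 to 1056 RPKM), PA3416 and PA3415, annotated as pyruvate dehydrogenase and dihydrolipoamide acetyltransferase components, rose from 5.3 to 648 RPKM and from 7.74 to 758 RPKM. All 5 genes around the propionate (methylcitrate) genes prpB, prpC and prpD rose (median 2.37), as did 9 of 9 listed genes of the histidine utilisation region (1.82), 8 of 8 of the Flp pilus and PprAB region (2.64) and 4 of 4 of the homogentisate region (1.41). The ribosome modulation factor gene rmf, whose product inactivates ribosomes in resting cells, rose from 9017 to 30566 RPKM, and the outer membrane lipoprotein gene oprI, the most abundant listed gene with FNA, rose from 12432 to 36894 RPKM. All 6 listed transposase genes rose with log2 ratios between 2.61 and 3.02, but near-identical copies can share reads, and how these were counted is not stated.

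Falls of similar coherence were seen outside the fixed lists. Beside the kdp operon (5 of 5 fell, median -4.48), the cluster from PA3327 to PA3336 fell in 10 of 10 genes (median -3.85). Malonate decarboxylation fell in 7 of 7 (-3.42), cytochrome c maturation in 8 of 8 (-2.50) and polyamine uptake and use in 9 of 9 (-1.99). In the regions of cobalamin synthesis 16 of 16 listed genes fell (-2.38). These regions include neighbours with other annotations, such as PA1271, a probable tonB-dependent receptor, and PA2943, an aldolase. All 11 translation factor genes fell (median -2.53), tufA and tufB among them, which are near-identical. Of 19 aminoacyl-tRNA synthetase genes 18 fell and argS rose from 36.5 to 86.8 RPKM. After centring, the medians of these groups stayed on the same side, at -3.31 for kdp and -0.82 for the polyamine genes, the smallest of them.

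The excess of falls over rises was weighed against abundance and scaling. The 25 genes highest with FNA held 17% of the listed RPKM in control and 37.7% with FNA. With equal sums over the other genes, the median log2 ratio was -0.93, with -0.87 at the upper end of the central 95% of 1000 resamplings of the genes, which does not clear the bound of -0.9 set before; it was -1.05 with 10 genes left out, -0.74 with 50, -0.55 with 100, -0.35 with 200 and -0.16 with 400. Since choosing genes by their level with FNA favours genes that rose, this drift is built into the choice and the test decides nothing, and a larger share taken by abundant rising genes stays open. A single scaling factor of the size of the median, -1.17, cannot be told apart from a true excess, since genes that did not change are not analysed here.

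The opposite courses of ribosomal protein and iron-sulfur cluster genes were set against a scaling factor and high expression. After centring the medians stayed on opposite sides, at -1.61 and 4.0, which a single factor does not produce. Against lists matched on mean RPKM, the ribosomal median of -2.78 lay below every random list and the iron-sulfur median at percentile 99.8, which argues against expression level as the cause. Those random lists drew genes singly, while the iron-sulfur genes form 1 operon and many ribosomal genes share operons. Genes of an operon can move together, so these percentiles can overstate how unusual the medians are. Slower growth of the treated cultures may underlie the ribosomal part: aminoacyl-tRNA synthetases had a median of -2.51, below the -1.17 of all listed genes. That test used values already seen, any change in growth would go with FNA in this design, and the hypothesis therefore stays open.

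Log2 ratios appeared to decline from the start to the end of operons, for example from nuoA (0.49) to nuoN (-2.80). Over 22 operons with at least 4 listed genes, 15 declined, with a median rank correlation of gene order and log2 ratio, across genes that are not independent, of -0.53. The 7 operons that had prompted the idea or had been picked for their changes are part of that figure; over the other 15, 9 declined with a median of -0.40, at percentile 2.78 of 10000 random orders, at the lower edge of their central 95% but inside it, so random order may account for them. Control RPKM itself declined along the operons with a median of -0.46. A decline equal in both conditions cancels in the ratio, and a falling denominator alone would raise it. This median therefore does not decide whether a property of distal genes in both conditions plays a part. Log2 ratios declined in 6 of the 8 operons without a control decline, but control RPKM is the denominator of the ratio. Choosing operons by it favours a declining ratio, so that count decides nothing. Of 5 operons whose median rose, 4 declined, too few to decide whether rising and falling operons are alike.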
